A study of Mus musculus with 98 samples.

How the data were processed

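Genomic DNA of G1-arrested Abelson-transformed mouse pre-B cells carrying site-specific breaks was treated with a single-stranded DNA ligase and with bisulfite, amplified by PCR and sequenced as read pairs on an Illumina MiSeq, per the labels and the series design. For each group of libraries the authors deposited a table of end structures with read counts, which are not normalised. Beside the count, each table holds a position and an overhang for each structure, both whole numbers read here as nt. The average insert size the authors list for each library has no stated unit and enters no test, since shorter inserts would follow from greater resection as well as from stronger amplification of shorter products. The aligner, the read filters and the genome build behind the tables are not given in the sources used here, so no genomic coordinates are printed, and gene symbols were looked up in a RefSeq gene table of assembly GRCm38.p6. Each table pools the 3 libraries of a group (1 for the KpnI control) and does not separate them. Of the 17 tables used, 15 list structures with 2 reads or more and 2 also list structures with 1 read. Another 2 tables held the same values as tables already used and were left out. For the Cas9 libraries the labels give sequencing run 8 and the list of read files gives set 9.

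The meaning of the columns was worked out from the data. The position was read as the place where the 5'-ending strand stops, and the 3'-ending strand was placed at the position minus the overhang. Positive overhangs were read as 3' overhangs, because the known KpnI end has a 4-nt 3' overhang and the main structure of its table has the value 4. Loss is the position minus a reference position, and all reference positions were set after seeing the data. For RAG breaks it was 2, the lowest position of either strand. For Cas9 it was 37, for the zinc finger nuclease 33 and for KpnI 127, the 5'-strand position of the most abundant structure with the overhang that enzyme is known to leave. If the true origin differs, all losses at that break shift alike. The tables do not say whether RAG ends are coding or signal ends. A coding end still closed as a hairpin would read as an end without loss. Losses beyond the amplified window are not measured: in the RAG tables the highest 5'-strand position was 173 to 183 at Jk1 and 208 to 209 at the substrate.

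Shares of reads were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Each share has an exact Clopper-Pearson 95% interval, which covers counting error only. A second 95% interval, added after seeing the data, came from 2000 resamples of the structures of a table. Resected ends had lost 10 nt or more from the 5'-ending strand. Line values were averaged with equal weight, and each mutant line was compared with each Lig4-/- line by a two-sided Fisher's exact test on pooled reads at a threshold of 0.05, over 180 pairs in 60 comparisons, without adjustment. A difference was called when all pairs lay on the same side and each passed. That rule for combining pairs was set after a first look at the tables. Because reads are not independent molecules, the smallest gap between genotypes is also set against the largest gap between lines of a genotype. Medians were compared without a test.

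Samples were grouped by genotype, cell line and break from the labels. The rule for naming structures was set together with the alternatives given below. It names the 3 structures with the highest share in each group, the 3 largest rises and the 3 largest falls in each genotype comparison among structures moving the same way against every Lig4-/- line, and the known ends of KpnI and Cas9. The classes fixed with it were blunt ends, 3' overhangs of 1 to 4, 5 to 9, 10 to 19 and 20 nt or more, 5' overhangs of 1 to 4 and 5 nt or more, ends without loss on either strand, and ends with 10 nt or more lost on both.

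Alternatives set before the data were examined counted each structure once, kept structures with 2 or 10 reads or more, left out the most abundant structure or each cell line in turn, used thresholds of 5 and 20 nt, counted both or either strand, called ends with 1 nt of difference blunt, used only sequencing run 4, and took medians over all ends. Added after seeing the data were position 37 for the zinc finger nuclease, equal weights over bins of 20 nt, leaving out the 10 most abundant structures, and counting once only structures with 2 reads or more where tables differed in the fewest reads they list. The calculation was tested on simulated data. Reads of 16 tables were redrawn 50 times each with the resected share set to a known value. It was recovered within 0.441 points, and the binomial interval held it in at least 43 of 50 draws. The redrawn reads were independent of each other, unlike PCR reads. The simulation thus checks the arithmetic and not how well the intervals cover these data.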

Results

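HCoDES (hairpin capture of DNA end structures) reads the structure of chromosomal double-strand breaks (DSBs). A single-stranded DNA ligase seals the strands of a broken end into a hairpin, bisulfite treatment keeps that hairpin from blocking amplification, and paired-end sequencing of the PCR product then shows where each strand of the end stopped. The cells were mouse pre-B cells transformed by the Abelson kinase and arrested in G1. All lines except the KpnI control, whose genotype the labels do not give, lacked DNA ligase IV (gene Lig4), the ligase of non-homologous end joining, so that broken ends stay unjoined. Some lines also lacked the histone variant H2AX (H2ax) or the DNA damage response protein 53BP1 (Trp53bp1). Breaks were made by the RAG recombinase at the Jk1 segment (Igkj1) of the immunoglobulin kappa locus or at a chromosomal recombination substrate, by Cas9 with a guide named Eb, or by a zinc finger nuclease (ZFN).

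The 98 sequenced files came from 49 libraries, each with a pair of read files, and fell into 17 groups. Of these groups, 16 held 3 libraries and the KpnI control held 1. Each group's table pooled its libraries, so no spread between libraries could be computed, and the cell line was the replicate. Lines of a genotype were not handled alike in every respect the sample titles record. At the RAG breaks the titles of Lig4-/- line B and of 53BP1-deficient line C carry the tag shNT, which the labels do not explain, and those of the other lines do not. The titles give 48 h for the RAG breaks of both Lig4-/- lines, 53BP1-deficient line B and H2AX-deficient line 8, and no time for H2AX-deficient line 5 or 53BP1-deficient line C. The title of 1 library of 53BP1-deficient line C at the substrate also names H2AX-deficient line 5, and it was grouped by its description. The descriptions of that library, of the KpnI control and of the 3 libraries of the de novo PCR say that their reads were mixed with those of another PCR and are to be separated by primer. The tables do not show how completely that was done. Reads per table ran from 68969 for the de novo PCR of H2AX-deficient line 8 to 715311 for Cas9 in Lig4-/- line A. Each table listed end structures, each defined by where the 5'-ending strand and the 3'-ending strand stopped. Shares are given as percent of reads with exact Clopper-Pearson 95% intervals. PCR reads without molecular identifiers are not independent molecules, so those intervals cover counting error only. A second interval, added after seeing the data, resampled the end structures of a table and was far wider. An end was called resected when its 5'-ending strand had lost 10 nt or more.

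The KpnI control asked whether the assay returns a known end, since KpnI leaves a 4-nt 3' overhang. The sign of the overhangs and the KpnI position were read from this table, so only the concentration of reads in 1 structure with an overhang of 4 nt was open to the comparison. That structure held 99.2% of 307425 reads (95% interval 99.19 to 99.26). The next structure, a 13-nt 5' overhang, held 0.0869% (0.0767 to 0.0979). All blunt structures together held 0.0504% of reads, and all 5' overhangs together held 0.420%.

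At Jk1 the preferred structures of Lig4-/- cells lay within a few nucleotides of the lowest position in the tables, which was taken as the break. The tables do not define it, and another origin would shift all losses alike. The 5'-ending strand had lost exactly 4 nt in 40.4% of reads of line A and in 30.2% of line B. The 3'-ending strand of those ends varied. The blunt structure with 4 nt lost from both strands held 12.1% of line A reads (12.0 to 12.2) and 7.49% of line B reads (7.40 to 7.59). The structure with a 4-nt 3' overhang, with 4 nt lost from the 5'-ending strand and none from the 3'-ending strand, held 9.66% and 8.25%. The third structure was a 1-nt 3' overhang in line A, at 6.29%, and a 2-nt 3' overhang in line B, at 4.89%. Ends with no loss on either strand held 4.69% and 2.92%. At the substrate the preferred 5'-strand position was 2 nt from the end, with 19.3% of line A reads and 19.2% of line B reads. Its leading structure was a 2-nt 3' overhang with no loss on the 3'-ending strand, at 9.07% (8.97 to 9.16) and 8.06% (7.91 to 8.21). Ends with no loss on either strand held 5.32% and 3.97% there, and a 1-nt 3' overhang with 2 nt lost from the 5'-ending strand held 5.05% and 4.08%.

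**Figure D1:**
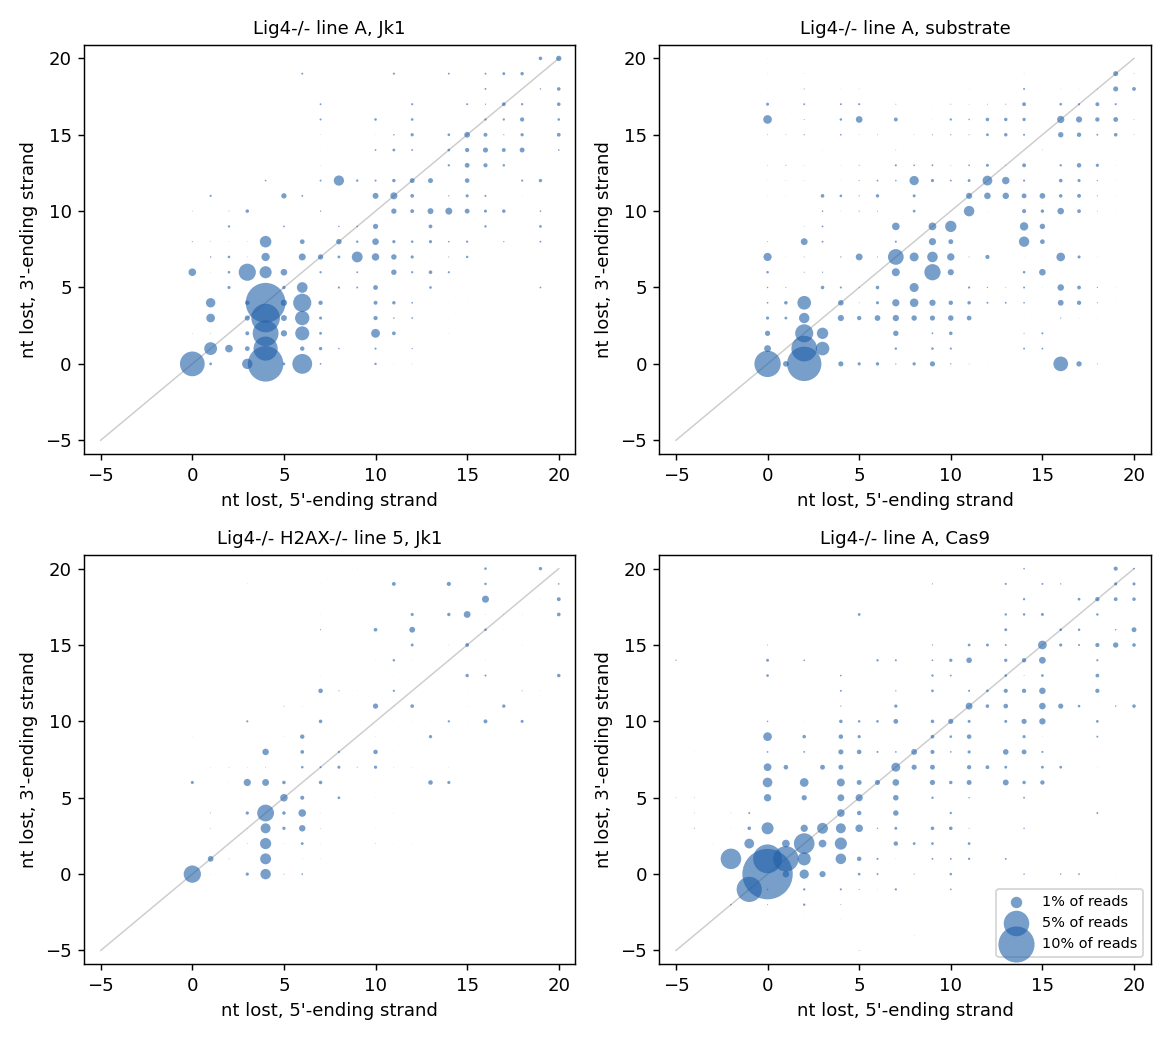
End structures close to the break in 4 tables. Each point is a structure, with nt lost from the 5'-ending strand on the horizontal axis and nt lost from the 3'-ending strand on the vertical axis, and its area is the share of reads; points on the diagonal are blunt and points below it have 3' overhangs. At Jk1 in Lig4-/- line A a column of structures stands at 4 nt lost from the 5'-ending strand (40.4% of reads), while the same column is small in H2AX-deficient line 5 (6.35%).

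At Jk1 a larger share of reads came from resected ends in H2AX-deficient cells than in Lig4-/- cells, a gap that shrank without the most abundant structures. Resected ends made up 85.8% ± 2.75 (SD, n = 2 lines) of reads in the H2AX-deficient lines and 43.4% ± 15.5 (SD, n = 2 lines) in the Lig4-/- lines. The values per line were 87.8% in line 5, 83.9% in line 8, 32.4% in Lig4-/- line A and 54.4% in line B. The smallest gap between a mutant line and a Lig4-/- line, 29.5 percentage points, exceeded the largest gap between lines of 1 genotype, 22.0 points. Without the 10 most abundant structures of each table, a setting added after seeing the data, the smallest gap was 5.50 points. The resected share was then 90.6% in line 5, 89.4% in line 8, 67.2% in Lig4-/- line A and 83.9% in line B. The 3 leading structures of each Lig4-/- table at the RAG breaks had lost less than 10 nt. Leaving them out raises the Lig4-/- share by construction, so the smaller gap does not show that a few structures carry it. The median loss from the 5'-ending strand was 112 and 127 nt in lines 5 and 8, against 4 and 13 nt in Lig4-/- lines A and B. The 3'-ending strand had been lost as well: ends with 10 nt or more missing from both strands held 85.2% ± 2.80 (SD, n = 2 lines) against 39.7% ± 15.8 (SD, n = 2 lines).

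The classes of end at Jk1 moved with it. The share of 3' overhangs was 36.4% ± 4.60 in H2AX-deficient lines and 58.1% ± 0.132 in Lig4-/- lines (SD, n = 2 lines each), and the share of 5' overhangs was 54.2% ± 2.65 against 23.2% ± 3.96. The drop in 3' overhangs lay in those of 1 to 4 nt, which held 17.6% against 46.0%. By contrast 3' overhangs of 20 nt or more held 5.51% against 1.40%, with every mutant line above every Lig4-/- line. For 3' overhangs of 5 to 9 nt the lines overlapped, at 7.19% ± 2.63 against 9.18% ± 0.264. The median 3' overhang was 7 and 4 nt in lines 5 and 8 and 3 nt in both Lig4-/- lines, a difference within the spread between the H2AX-deficient lines. Over all ends, with blunt ends as 0 and 5' overhangs as negative lengths, the median overhang was lower in the H2AX-deficient lines, by -2 nt. The largest falls among structures were near the break. The 4-nt 3' overhang fell from a mean of 8.96% to 1.12%, and the blunt end 4 nt inside fell from 9.81% to 2.88%. A 1-nt 3' overhang with the same 5' end was the next, at 4.89% against 0.769%. The largest rises were 5' overhangs far inside. A 4-nt 5' overhang starting 135 nt in rose from 1.10% to 3.50%, a 4-nt 5' overhang at 125 nt from 0.502% to 2.77%, and a 1-nt 5' overhang at 137 nt from 0.582% to 2.38%. The last rested on line 8, at 3.73%, since line 5 was at 1.03% and the higher Lig4-/- line at 0.898%.

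For the shares of resected ends, of all 3' overhangs and of all 5' overhangs at Jk1, every pair of tables differed in Fisher's exact test, two-sided, with p too small for a double-precision number. For 3' overhangs of 5 to 9 nt, line 5 did not differ detectably from Lig4-/- line A (Fisher's exact p = 0.571). That test compares those pools of reads and not the conditions. With 2 lines against 2, an exact permutation test of line values cannot give a p below 0.333. When each distinct structure was counted once in place of its reads, the resected share differed by 2.51 points and the 3' overhang share by -5.88 points, and neither passed in every pair of lines (largest Fisher's exact p = 0.256 and p = 0.634). When structures were resampled, the intervals of the resected share stayed apart, with a lowest bound of 74.7% in line 8 and a highest of 71.0% in Lig4-/- line B. Those of the 3' overhang share overlapped, at 32.6 to 47.5% in line 5 and 38.2 to 75.7% in Lig4-/- line A.

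At the substrate the same comparison gave 94.5% ± 2.12 resected ends in H2AX-deficient lines and 56.95% ± 1.29 in Lig4-/- lines (SD, n = 2 lines each). Its smallest gap of 35.1 points exceeded the 2.99 points between lines of a genotype, and was 15.4 points without the 10 most abundant structures of each table. The median 5'-strand loss was 128 and 150 nt in lines 5 and 8 and 13 nt in both Lig4-/- lines. Blunt ends fell from 18.7% ± 0.297 to 11.1% ± 2.57, beyond the spread between lines, but the intervals from resampled structures overlapped (8.29 to 18.99% in line 8, 8.58 to 30.9% in Lig4-/- line A). The 5' overhang share was 37.2% ± 6.22 against 23.4% ± 5.50, with a smallest gap of 5.49 points that was within the 8.79 points between lines of a genotype. The share of 3' overhangs did not separate the genotypes: it was 57.9% in line 5 and 45.5% in line 8, against 61.9% in line A and 53.8% in line B. Over lines it differed by -6.17 points. Without line 8, which also restricts the comparison to the sequencing run shared with the Lig4-/- lines, it differed by 0.0427 points. Without line 5 it differed by -12.4 points and without Lig4-/- line B by -10.3 points, and in both cases all remaining pairs passed. Ends with a 2-nt 3' overhang at 2 nt fell from 8.56% to 0.778%, the 1-nt 3' overhang there from 4.57% to 0.429%, and ends with no loss from 4.64% to 1.11%. The blunt end 170 nt inside rose from a mean of 0.960% to 2.84%, but Lig4-/- line A, at 1.91%, was close to H2AX-deficient line 8, at 2.12%, while line B was at 0.00702%. The other structures with the largest rises were a 3-nt 5' overhang at 176 nt (0.0218% to 1.75%) and a 5-nt 3' overhang at 168 nt (0.000454% to 1.13%), and the first of these rested on line 5, at 3.47%, with line 8 at 0.0370%. The H2AX-deficient lines held 0.691% and 1.56% of the second. The resected share, each structure counted once, differed by 3.92 points and did not pass in every pair (largest Fisher's exact p = 0.191).

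**Figure D2:**
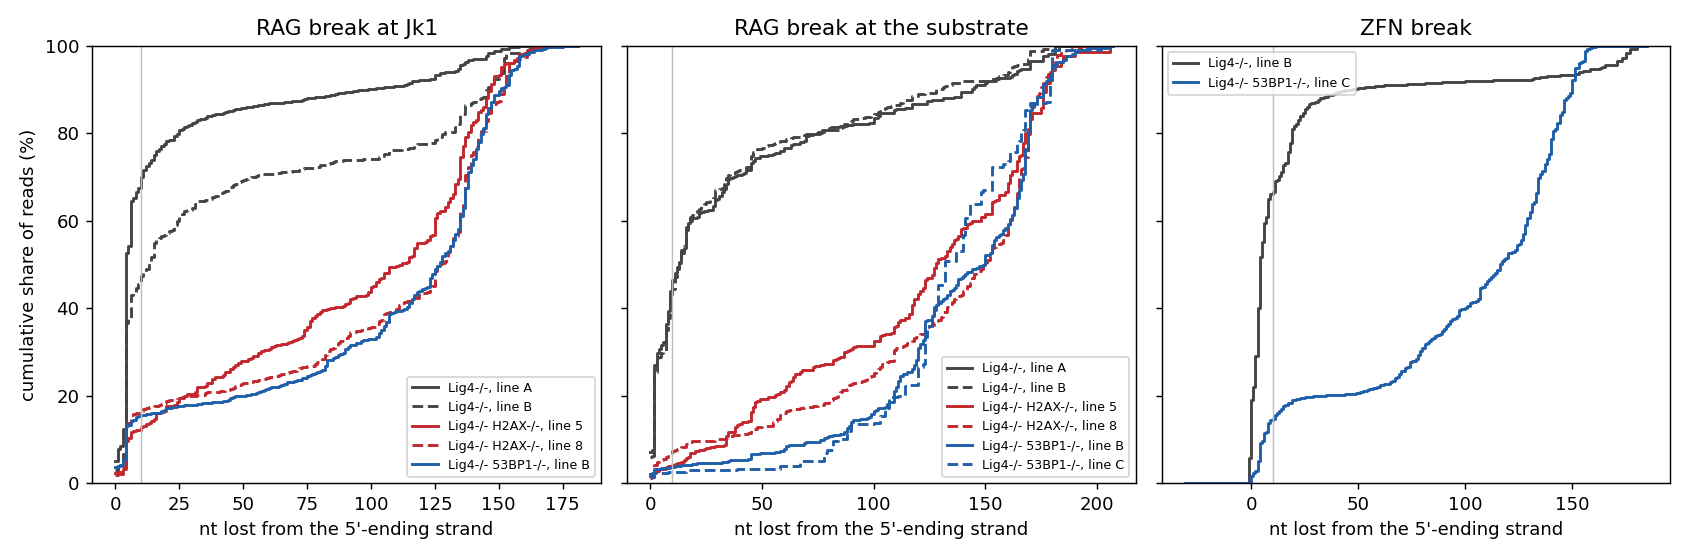
Cumulative share of reads (percent, vertical axis) against nt lost from the 5'-ending strand (horizontal axis) at RAG breaks at Jk1, at RAG breaks at the substrate and at the ZFN break. Each line is the pooled table of a cell line, and the grey vertical line marks the 10-nt threshold. At the RAG breaks 32.4 to 57.9% of reads of the Lig4-/- lines lie at 10 nt or beyond, against 83.9 to 97.53% in the H2AX- and 53BP1-deficient lines.

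Loss of 53BP1 was compared in the same way. At Jk1, 84.6% of reads of 53BP1-deficient line B were resected (84.5 to 84.8), against 43.4% ± 15.5 (SD, n = 2 lines) in Lig4-/- cells. The gap to the nearer Lig4-/- line was 30.2 points. Without the 10 most abundant structures of each table the shares were 91.6% in line B of this genotype and 83.9% in that Lig4-/- line. Its 5' overhangs held 63.3% of reads and its 3' overhangs 27.4%, against means of 23.2% and 58.1%. Overhangs of 5 nt or more on the 5' side held 41.1%, against 7.10% ± 3.61 in the Lig4-/- lines, and 3' overhangs of 20 nt or more held 9.98% against 1.40% ± 0.497. The median 3' overhang was 10 nt against 3 nt, a difference that was 3.5 nt with each structure counted once and -4 nt over all ends. The largest falls were the 4-nt 3' overhang at 4 nt, from 8.96% to 1.30%, the blunt end at 4 nt, from 9.81% to 2.78%, and the 2-nt 3' overhang at 4 nt, from 5.00% to 0.732%. The largest rises were a 9-nt 5' overhang at 123 nt, from 0.110% to 1.55%, a 5-nt 5' overhang at 143 nt, from 0.119% to 1.46%, and the 1-nt 5' overhang at 137 nt, from 0.582% to 1.59%. Ends with no loss on either strand stayed between the Lig4-/- lines, at 3.29%. With each structure counted once, the difference in resected ends was 4.99 points in place of 41.2, and that in 3' overhangs -10.8 in place of -30.7. Only 1 line of this genotype was measured at Jk1, so an exact permutation test of line values cannot give a p below 0.333.

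At the substrate 2 53BP1-deficient lines were measured. Resected ends held 96.9% ± 0.874 against 56.95% ± 1.29 (SD, n = 2 lines each), with a smallest gap of 38.4 points. Without the 10 most abundant structures, the nearest lines were 53BP1-deficient line C at 95.9% and Lig4-/- line B at 77.8%. With each structure counted once, the difference was 7.53 points in place of 40.0, and 7.69 points with only structures of 2 reads or more. Overhangs of 5 nt or more on the 5' side held 35.7% ± 2.52 against 9.16% ± 3.59. Those of 1 to 4 nt did not separate the genotypes, with 21.9% in line B, 6.17% in line C and 12.9% and 15.6% in Lig4-/- lines A and B. For all 5' overhangs the smallest gap of 12.8 points was within the 19.3 points between lines of a genotype. Blunt ends held 8.34% ± 1.76 against 18.7% ± 0.297, with overlapping intervals from resampled structures (4.71 to 15.6% in line B, 8.58 to 30.9% in Lig4-/- line A). The share of 3' overhangs was 30.96% in line B and 52.8% in line C, so the lines of this genotype differed by more (21.8 points) than line C did from the nearer Lig4-/- line (-0.967 points, Fisher's exact p = 9.69e-07 on the reads). The mean difference of -15.98 points became -5.07 without line B and -26.9 without line C, which also restricts it to 1 sequencing run. It no longer passed in every pair of lines with the most abundant structure of each table left out (-13.5 points, largest Fisher's exact p = 0.0901), with structures counted once (-5.09 points, p = 0.420), or with ends of 1 nt difference called blunt (-4.96 points), where the pairs were no longer all on the same side. Median 3' overhangs of 12 and 6 nt in lines B and C stood against 3 and 2 nt in Lig4-/- lines A and B, and over all ends the median differed by -1 nt. The 2-nt 3' overhang at 2 nt fell from 8.56% to 0.190%, the 1-nt 3' overhang from 4.57% to 0.261% and ends with no loss from 4.64% to 1.53%. Each of the largest rises rested on line C. A 12-nt 3' overhang at 179 nt held 5.05% there and 0.740% in line B, a 29-nt 5' overhang at 153 nt held 4.23% and 0.00207%, and an 11-nt 5' overhang at 140 nt held 3.66% and 0.000888%. Line C was sequenced in another run, and its table also listed structures with 1 read.

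The ZFN break was measured in Lig4-/- line B and 53BP1-deficient line C, in different runs. The number after the tag ZF also differs between their titles, and the labels do not explain it. Line, run, ZF number and genotype thus cannot be told apart. A 4-nt 5' overhang is the end the FokI domain of the ZFN is known to leave. The most abundant structure of that kind in line B, at 4.67% of reads (4.62 to 4.72), was taken as the break position after seeing the data. A 2-nt 5' overhang starting 1 nt outside it held 5.66%, and a 2-nt 5' overhang 4 nt inside held 4.91%. Resected ends held 33.8% in line B (33.7 to 33.9; 25.3 to 46.4 when structures were resampled) and 85.6% in line C (85.6 to 85.7; 80.4 to 90.4 when structures were resampled). The 5' overhang share was 51.2% in line B and 73.6% in line C, and the 3' overhang share was 39.4% and 18.9%. With each structure counted once, the difference in resected ends was 3.50 points in place of 51.9, and that in 3' overhangs -9.10 in place of -20.5. Of the 1804 structures listed in line B, 617 had 1 read, while line C lists none with 1 read. With only structures of 2 reads or more counted once, a setting added after seeing the data, the differences were 4.90 and -10.2 points. The 5' overhangs of 5 nt or more held 2.76% of reads in line B and 34.1% in line C, while those of 1 to 4 nt held 48.4% and 39.5%. The 4-nt 5' overhang at the break position was not listed in line C, so a break position shared by both lines was not shown. The 2-nt 5' overhangs fell to 0.0180% outside and 0.469% inside. The largest rises were a 5-nt 5' overhang at 134 nt, to 1.22%, a 6-nt 5' overhang at 4 nt, to 1.08%, and a 5-nt 5' overhang at 141 nt, to 1.06%. A 3-nt 5' overhang at 3 nt was also among the leading structures of line C, at 1.15%.

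**Figure D3:**
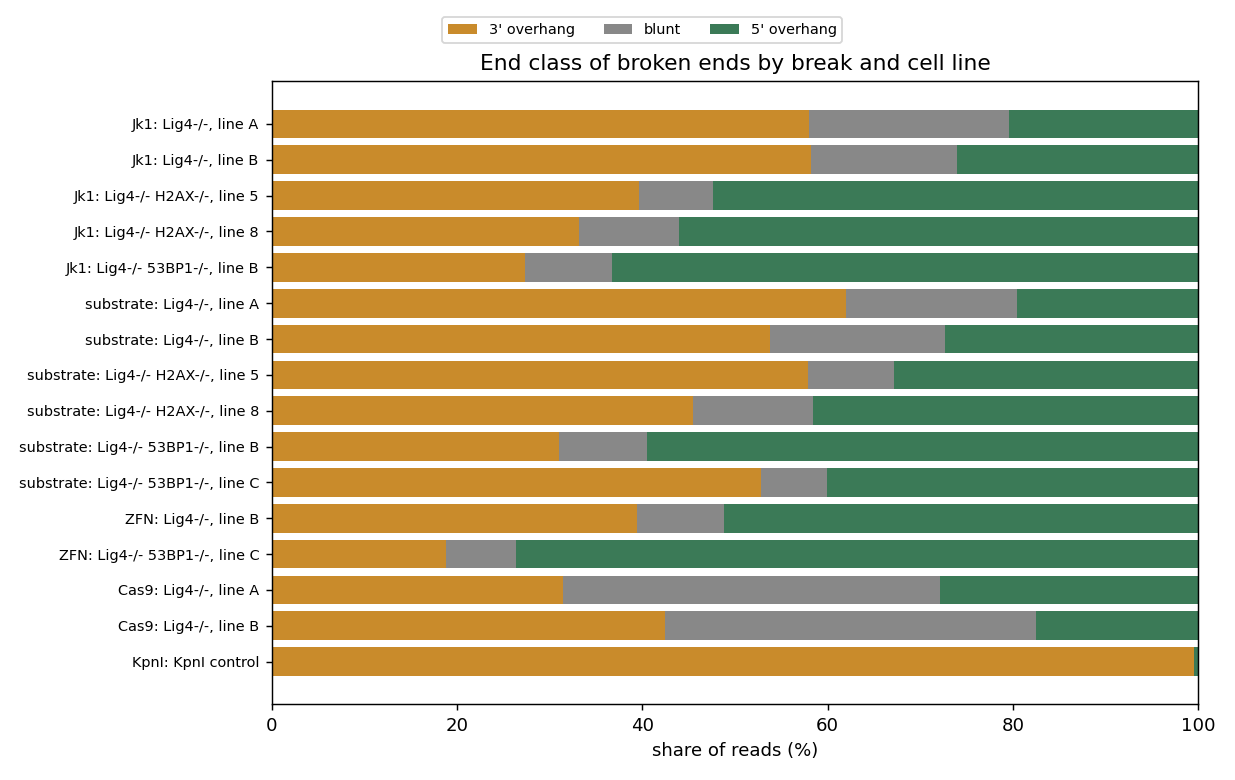
Share of reads (percent, horizontal axis) with a 3' overhang, a blunt end or a 5' overhang in each table except that of the de novo PCR, grouped by break and cell line. Bars add to 100% and carry no error bars because each is 1 pooled table. Among the tables drawn, the 5' overhang segment is widest at the ZFN break in 53BP1-deficient line C (73.6%), followed by Jk1 in 53BP1-deficient line B (63.3%), and blunt ends are widest at the Cas9 break (40.7% and 40.0%).

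By reads, Cas9 breaks in Lig4-/- cells held a larger share of blunt ends than RAG breaks. The Cas9 and ZFN breaks lay in other amplicons and were sequenced in other runs than the RAG breaks of the same lines, so nuclease, locus and run cannot be told apart. Blunt ends held 40.7% of reads in line A (40.6 to 40.8) and 40.0% in line B (39.9 to 40.1), against 15.8 to 21.6% at the RAG breaks of the same lines. When structures were resampled, the intervals were 14.8 to 61.1% and 14.5 to 62.1% at the Cas9 break, which overlapped those of the RAG breaks, such as 4.14 to 41.5% for line A at Jk1. The blunt end at the most used position, taken as the cut, held 19.5% and 21.7%, and a 1-nt 5' overhang with its 5' end there held 6.38% and 4.57%. The third structure was a blunt end 1 nt inside in line A, at 4.95%, and 1 nt outside in line B, at 4.35%. The lines differed by -0.695 points in blunt ends, but by 11.1 points in 3' overhangs (31.4% in line A, 42.5% in line B). Resected ends held 36.4% and 37.4%. The mean excess of blunt ends over RAG breaks was 21.6 points, and 7.63 points without the most abundant structure of each table. Counting each structure once, the excess was 1.94 points and did not pass in every pair (largest Fisher's exact p = 0.762), and the ZFN excess of 5' overhangs over RAG breaks, 27.8 points by reads, became 5.89 points (largest Fisher's exact p = 0.0651), or 3.87 points with only structures of 2 reads or more (p = 0.394).

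Both RAG breaks could be compared within 5 lines. Their amplified windows differ, with highest 5'-strand positions of 173 to 183 at Jk1 and 208 to 209 at the substrate. Losses beyond them are not measured, so break site and window cannot be told apart. Resected ends were less common at Jk1 than at the substrate in all 5, by -3.47 points in Lig4-/- line B to -23.6 points in line A, with a mean of -11.2 points. An exact permutation test over the 5 paired line differences, two-sided and added after seeing the data, gave p = 0.0625, the smallest it can give with 5 lines. The difference was no longer on the same side in all 5 lines with a threshold of 20 nt (mean -8.63 points) or with losses of 10 nt required on both strands (mean -9.18 points, Lig4-/- line B 1.19 points), and with structures counted once the mean was 2.49 points. The 3' overhang share was lower at Jk1 in 4 lines, by -3.59 to -18.2 points, and higher by 4.45 points in Lig4-/- line B. The same permutation test gave p = 0.25 for it. Its mean of -6.71 points became -9.51 without that line and -3.84 without H2AX-deficient line 5. The Lig4-/- lines differed from each other by 22.0 points in resected ends at Jk1, with line B higher, and by 1.82 points at the substrate. Line and shNT tag cannot be told apart in this comparison. Their 3' overhang shares at Jk1 differed by 0.186 points (Fisher's exact p = 0.137). The average insert size the authors list, without a unit, was lower in every group of H2AX- or 53BP1-deficient lines at the RAG breaks (188 to 278) than in every group of Lig4-/- lines there (386 to 426), and was 284 against 403 at the ZFN break.

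In H2AX-deficient line 8 a further PCR at the substrate was labelled as measuring de novo DSBs. The titles of its 3 libraries also carry the tag B5L, which the labels do not explain. A like tag, C5L, stands in the titles of the ZFN libraries of line C, which lacks Trp53bp1. The tag B5L may thus name line B of that genotype. The descriptions say that the de novo reads were mixed with those of the regular substrate PCR. Whether reads of another line remain in this table was not tested. The de novo titles give no time, while those of the substrate PCR of line 8 give 48 h. The number after the line name also differs between these titles. The de novo PCR was sequenced in run 5 and the substrate PCR of that line in run 2. PCR, run and these differences cannot be told apart. The libraries were grouped by their descriptions. Of its 68969 reads, 26.5% had 3' overhangs (26.2 to 26.9; 10.5 to 46.9 when structures were resampled), 8.99% were blunt and 64.5% had 5' overhangs, against 45.5% (39.1 to 51.99 when structures were resampled), 12.9% and 41.6% in the substrate PCR of that line. The wider intervals of the 3' overhang share thus overlap. A single structure, a 37-nt 3' overhang between positions 121 and 158 of the table, held 14.04% of reads (13.8 to 14.3). Without the most abundant structure of each table, the 3' overhang share differed from that of the substrate PCR by -31.9 points in place of -18.9. The next structures were a blunt end at position 161 with 2.05% and a 4-nt 5' overhang at position 127 with 1.85%. No break position is defined for this PCR, so no loss was computed.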

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

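Among the alternatives given here, the zinc finger nuclease position of 37 and counting once only structures with 2 reads or more were chosen after the result was seen, as were the reference positions and the rule for combining pairs that all of them share. With position 37 resected ends differed by 53.8 points between 53BP1-deficient and Lig4-/- cells. Of 196 alternative values, 28 only repeated another value, because the minimum of 2 reads or the limit to run 4 removed nothing or the same line as a value without that line. Of the other 168, 135 counted as the same. They kept their direction and, with a test, their side of the threshold or, without one, a place within the spread. Calls were lost in 12 and gained in 3. Another 7 changed direction, and 11 without a test moved beyond the spread. That spread was the SD between lines of a genotype, or for the KpnI control the counting error of its share. Fisher's exact test on this many reads passes small differences (-0.967 points, p = 9.69e-07), so alternatives that count reads could seldom lose the call. With each structure counted once, 8 of 21 values were the same, 6 lost the call, 5 moved and 2 changed direction. Unless stated, the cause was not tested. Resected shares of the mutant lines kept their direction under every alternative run, from 2.51 to 53.4 points for H2AX and 4.99 to 52.2 for 53BP1 at Jk1, 3.92 to 52.8 and 7.53 to 57.2 at the substrate, and 3.50 to 62.0 at the zinc finger nuclease break. With each structure counted once, the H2AX differences in resected ends of 2.51 at Jk1 and 3.92 at the substrate lost the call, as did the 3' overhang shares of H2AX at Jk1 (-5.88) and of 53BP1 at the substrate (-5.09), the blunt excess of Cas9 over RAG breaks (1.94) and the 5' overhang excess of the zinc finger nuclease (5.89). With only structures of 2 reads or more counted once, the 53BP1 difference in 3' overhangs (-4.85) and the zinc finger nuclease excess (3.87) lost the call too, and the 53BP1 median at the substrate moved to 1.5 nt. The resected share at Jk1 minus substrate turned to 2.49, the blunt share at Cas9 moved to 7.94% and the KpnI structure to 0.694%. Median 3' overhangs moved to 0.5 nt (H2AX) and 3.5 nt (53BP1) at Jk1 and to 2.5 nt (53BP1) at the substrate, and turned to -1 nt for H2AX there. Counting structures once also lowers the number tested from reads to structures, and few distinct structures can lie within 10 nt of a break. Medians over all ends, which by construction fall when 5' overhangs rise, were -2 nt (H2AX) and -4 nt (53BP1) at Jk1, and 0 and -1 nt at the substrate. With 1 nt tolerance for blunt ends, the 3' overhang share at the substrate differed by 0.553 points for H2AX and -4.96 for 53BP1, and the Cas9 blunt share was 56.8%. Without the most abundant structure, the 53BP1 value was -13.5, the Cas9 blunt share 24.8% and the KpnI structure 0%, since it is the one left out. With 10 reads or more the KpnI structure held 99.3%. Within sequencing run 4 the H2AX difference in 3' overhangs at the substrate was 0.0427, and leaving out each line gave -12.4 to 0.0427. For Jk1 minus substrate, resected ends gave -8.63 with 20 nt and -9.18 with both strands, and 3' overhangs gave -9.51 to -3.84 when each line was left out. Between libraries, no paired analysis was possible because replicate numbers only follow the order of the sample list and the tables do not separate libraries. Break sites were paired within cell lines. Leaving out libraries could not be run for that reason, and the second copies of 2 tables gave no alternative because their values were equal. Depth leaves counting error small, but the number of independent molecules behind the reads is unknown.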

Other observations

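The tests of product length, mix of end positions, carry-over and chance overlap were chosen only after the result was seen, as was the bound in the test of sequencing run, whose restriction to run 4 was set beforehand; leaving out the 10 most abundant structures was taken up after counting structures once had shrunk the gap, and the condition that a resampling interval exclude the forbidden value was added to the tests of position mix, shared structures and carry-over after their first values were seen.

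Among ends that had lost less than 10 nt at Jk1, blunt ends held 27.9% of reads in Lig4-/- line A and 24.7% in line B. They held 42.8% and 34.1% in H2AX-deficient lines 5 and 8 and 42.2% in 53BP1-deficient line B. These blunt ends include the structure with no loss on either strand, which a coding end still closed as a hairpin would mimic. Among ends that had lost less than 10 nt, it held 8485 of 39684 reads in 53BP1-deficient line B. In H2AX-deficient line 5 it held 3922 of 20872. The blunt share without it was not computed, and no interval over structures was made, so a shift among other blunt ends is not shown. At the substrate the lines did not all go the same way. Blunt ends held 23.7% and 26.4% in Lig4-/- lines A and B, 35.6% in H2AX-deficient line 5 and 21.4% in line 8, and 58.1% and 41.9% in 53BP1-deficient lines B and C.

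The higher resected share of H2AX- and 53BP1-deficient lines could be technical. Sequencing run as the whole cause is argued against, since within run 4, which holds H2AX-deficient line 5 and 53BP1-deficient line B, the smallest gap was 30.2 points at Jk1 and 38.1 at the substrate. A few structures with many reads cannot be told apart from a broad shift by the tests run. Without the 10 most abundant structures of each table every mutant line stayed above every Lig4-/- line. The smallest gap was then 5.50 points at Jk1 and 15.4 at the substrate. That setting cannot decide, because the 3 leading structures of each Lig4-/- table there had lost less than 10 nt. Leaving them out raises the Lig4-/- resected share by construction. Counting structures once gave mean gaps of 2.51 and 3.92 for H2AX, which lost the call. For 53BP1 it gave 4.99 and 7.53, which kept it but rest on tables listing unequal numbers of structures (at Jk1, 1070 in 53BP1-deficient line B, 745 and 678 in the Lig4-/- lines). It has a like limit, since few distinct structures can lie within 10 nt of a break. Stronger amplification of shorter products stays open too, because a rise with loss in the ratio of mutant to Lig4-/- share among ends that had lost 20 nt or more (median rank correlation 0.85 over 14 pairs of tables that reuse 4 Lig4-/- tables) would also follow from greater resection, as would the lower insert sizes the authors list for the mutant libraries (188 to 278 against 386 to 426 at the RAG breaks), and the correlation was only 0.0476 to 0.310 in the 3 pairs with Lig4-/- line B at Jk1. The loss of H2AX or 53BP1 remains among the open explanations.

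The higher 5' overhang share of the mutant lines at Jk1 might follow from where their ends lie. With equal weights over bins of end position the smallest gap was 7.52 points, for H2AX-deficient line 5 against Lig4-/- line B, and its interval of -2.61 to 17.8 included 0, so a different mix of end positions cannot be told apart from a change in end class for that line. Intervals lay above 0 for H2AX-deficient line 8 (gaps of 13.1 and 13.5 points) and for 53BP1-deficient line B (18.7 and 19.1 points). These gaps are means over 8 bins and did not hold in each. Every mutant line exceeded both Lig4-/- lines in the bins from 0, 20, 100 and 140 nt. In those from 40, 60, 80 and 120 nt the lines overlapped. From 60 nt, 5' overhangs held 31.3% and 38.5% in H2AX-deficient lines 5 and 8, against 48.1% and 52.8% in Lig4-/- lines A and B. The structures found in all 5 tables are argued against as the source, since without them the smallest gap was 18.6 points (interval 7.75 to 29.2). The removal was uneven. Those structures held 73.0% and 55.8% of reads in Lig4-/- lines A and B, against 28.3 to 36.3% in the mutant lines. The genotype remains an open explanation.

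Many structures 20 nt or more from the break recurred at Jk1, with 48 present in all 5 tables. In 1000 draws that permuted overhangs within each table there were at most 5 such structures, with a mean of 0.972. This argues against chance overlap of positions and overhangs that are independent of each other. Overhang did depend on position: in all 5 tables every read with 160 to 179 nt lost had a 3' overhang. These ends lay near the far edge of the amplified window, whose part in this was not tested. The draws broke the link between overhang and position, so they cannot exclude chance overlap given the positions each strand prefers. Carry-over of reads within a sequencing run could not be decided. Of the 50 most abundant far structures of H2AX-deficient line 8, from another run, 44% were also present in the Lig4-/- tables. For line 5, from the same run, the share was 46% (ratio 0.957, interval 0.638 to 1.39). Line 8 itself could not have passed reads on within that run. It shared leading far structures with line 5, however, such as the 4-nt 5' overhang at 135 nt (3.46% and 3.53%). Reads carried over from line 5 into the Lig4-/- libraries would thus also place structures of line 8 there. No biological explanation was tested for this recurrence, and a sequence preference of the amplification could not be examined without the sequence.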
